A study of Mus musculus with 6 samples.

How the data were processed

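The data were 6 Affymetrix arrays of mouse liver RNA, 1 of the 430A and 1 of the 430B design for each of 3 genotypes (WT, LT and 17kT). The deposited values are signal intensities on a linear scale, 1 per probe set, made with MAS5, per the submitters' processing notes, and the version is not given in the sources used here. The deposited intensities had been scaled by the authors, since the 2% trimmed mean was between 250.03 and 250.12 on every array. Values of the WT and LT arrays were given to 1 decimal and those of the 17kT arrays to more digits, so the 17kT arrays were exported differently. The authors also deposited a settings file per array, which holds other, non-expression entries (chip lot, fluidics station, scanner). Per the file headers, 1 chip lot per design, 1 scanner, 1 wash protocol and 1 scan day were used, and fluidics station 2 washed the LT arrays and station 1 the others. Whether an RNA sample came from 1 animal or a pool is not given in the sources used here.

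Probe sets were named from the platform annotation provided with the data, with symbols checked through gene identifiers against the RefSeq table of the GRCm38.p6 assembly. Gene positions in that table served only to find neighbouring genes, and no coordinates are printed. Of 22690 probe sets on 430A, 20393 had 1 gene symbol, 691 several and 1606 none. Of 22575 on 430B, the numbers were 14674, 245 and 7656. Probe sets with several symbols or none were not named or counted.

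Signals were scaled within each design to a common 2% trimmed mean, which changed little. They were then floored at the median of all scaled signals of the design (90.4 on 430A and 140.5 on 430B) and put on the log2 scale. Ratios were taken only within a design. Each gene was represented by the probe set with the highest mean signal relative to the floor of its design, and probe sets of the _x_at kind, which can bind several genes, served only where a gene had no other. This gave 18193 genes. A gene at the floor on both arrays had no direction, and a gene at the floor on 1 array gave a bound. With 1 array per group no test was possible, so genes were called at a fixed size, at least 2-fold, and the number of arrays limits the precision of every value.

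The 37 gene lists, 26 of pathways and 11 of cell type markers, were fixed before the data were examined, as were the rule of size, the floor and the rule for naming genes. Of 1148 list entries, 1038 matched a gene on the arrays and 110 were not analysed here. A list was described by the median log2 ratio of its members above the floor on at least 1 of the 2 arrays, with members at the floor on 1 array entering at their bound, and by the percentile of that median among 10000 random lists of the same size matched in 10 bins of brightness. The percentile describes these arrays and is no test. Lists with fewer than 5 measured genes were described by their genes. The genes named were, for each comparison, the 8 highest and 8 lowest ratios among genes above the floor on both arrays and without another probe set going the opposite way by 2-fold, the 3 brightest each way among genes at the floor on the other array, the list members with large ratios, and Cdkn1a, Mdm2, Ccng1, Trp53, E2f1, Rb1, Pcna, Mki67, Alb, Afp and Apoe. Outside this rule, and after their values were seen, Hamp, Mup3 and Peg3 were named in LT against WT, Fasn, Gtse1, Mt1 and Mt2 in 17kT against WT, and Cpt1a, Pdk4 and Gpc3 in LT against 17kT.

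Technical spread was taken from 100 probe sets present on both designs, as the SD of the difference between the log2 ratios of the designs divided by the square root of 2 values, and from pairs of probe sets of the same gene in the same way. The SD over the 100 probe sets leaves out any constant offset between the designs. Of 631 genes called in LT against WT that had a second probe set above the floor, 78.8% had a second probe set with the same sign, and 15 had one that went the opposite way by 2-fold. For 17kT against WT these were 79.6% of 550 and 11, and for LT against 17kT 75.8% of 248 and 4. The code was tested on simulated arrays with the mean signals of the real ones, noise of the size seen between probe sets of a gene, and 50 genes changed at each of 1.5-fold, 2-fold, 3-fold and 4-fold per comparison. The changed genes were drawn from measured genes with a mean signal over 2 times the floor. Overlap between the comparisons with WT was set beside 100 simulated draws with a shared WT array.

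The alternatives planned before the data were examined were 4 other scalings (the median of all probe sets, the probe sets shared by both designs, quantile normalization, and signals as deposited), a floor at the 25th or 75th percentile, the floor as a pseudocount, a 3-fold rule, the mean over the probe sets of a gene, leaving out _x_at and _s_at probe sets, and each design alone. Scaling to the bacterial and phage hybridisation controls was added after seeing the data. The median log2 ratio of these controls was -0.45 on 430A and -0.25 on 430B for LT against WT. It was -0.94 and -0.004 for 17kT against WT, and 0.41 and -0.29 for LT against 17kT. This scaling thus moved the 2 designs by unlike amounts. Leaving out a replicate was not possible with 1 array per group and design. As a check of sex, Xist, with probe sets on 430A only, lay at the floor there in every genotype. Of the Y-linked genes, Eif2s3y was above the floor on the 430A arrays (signals of 192, 192 and 248 for WT, LT and 17kT) and at the floor on the 430B arrays, Kdm5d was at the floor throughout, and Uty was at the floor in LT on each of its probe sets. The analysis used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.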

Results

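Liver transcripts were measured on Affymetrix mouse genome arrays in male mice of a hybrid B6SJL background, aged 32 to 37 days. Each of 3 genotypes gave 1 array of the 430A design and 1 of the 430B design, 6 arrays in all. WT mice carried no transgene. The other mice made viral oncoproteins of SV40, a polyomavirus, in the liver once doxycycline was given. LT livers were induced to make the large T antigen, which binds the retinoblastoma family of proteins and p53. 17kT livers were induced to make 17kT, a short form from an alternatively spliced message that keeps the retinoblastoma family binding motif and lacks the part that binds p53. Per the labels, both kinds of transgenic liver also made the small t antigen. The labels also name an ApoErtTA transgene in both, which WT mice lacked. Comparisons with WT cannot tell the effect of ApoErtTA apart from that of the viral proteins. All mice, WT included, drank doxycycline at 25 µg/ml with 2.5% sucrose for 4 days.

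The genotypes had no replicates, so no difference below has a replicate check, and no p-value is given. The transgene products were not measured here, so the arrays do not check the genotype labels. A gene was called higher or lower when its floored signal differed at least 2-fold between the arrays compared, that is by at least 1 on the log2 scale. "At least" before a fold marks a gene at the floor on the dimmer array. Of 22690 probe sets per 430A array and 22575 per 430B array, between 47.0% and 52.0% lay above the floor. The spread of a log2 ratio between 2 measurements of the same RNA, an error that is technical and not biological, was 0.23 for LT against WT, 0.28 for 17kT against WT and 0.26 for LT against 17kT (SD over 100 probe sets present on both designs). Between probe sets of the same gene it was 0.54, 0.52 and 0.45 (SD). The SD over the 100 probe sets present on both designs leaves out a constant offset between the designs. The median offset (430A minus 430B) was -0.25 for LT against WT, 0.19 for 17kT against WT and -0.36 for LT against 17kT. Of these 100 probe sets, 98 were above the floor on both designs, so this SD describes probe sets above the floor.

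The comparison of LT with WT asked how livers induced to make large T with small t differed from WT liver after 4 days. LT liver held far more transcript of genes for cell division and far less of genes for hepatocyte metabolism than WT liver. Top2a, the DNA topoisomerase of dividing cells, was 14.9-fold higher, the mitotic ubiquitin-conjugating enzyme Ube2c 14.3-fold, the mitotic cyclin Ccnb2 13.8-fold and the kinetochore motor Cenpe 11.2-fold. Afp, the fetal counterpart of albumin, was at least 85.3-fold higher. Thrsp, a regulator of fatty acid synthesis, was 61.0-fold lower, the cytochrome P450 genes Cyp1a2 32.0-fold and Cyp2e1 30.2-fold. In all, 1417 of 12775 measured genes were higher in LT and 1151 were lower.

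Among genes above the floor on both arrays, the remaining large increases in LT against WT were in Slpi, a secreted protease inhibitor (17.8-fold), D17H6S56E-5 (12.1-fold), the tubulin Tubb6 (11.7-fold) and the mitotic kinesin Kif20b (11.7-fold). Bex3 was at least 28.6-fold higher and Slc25a4, a mitochondrial ADP/ATP carrier, at least 19.4-fold. The remaining large decreases were in the acute phase gene Saa1 (57.8-fold), the sulfotransferase gene Sult2a8 (57.6-fold), Cyp2c50 (54.0-fold), Depp1 (49.7-fold) and Gulo, whose enzyme completes vitamin C synthesis (30.6-fold). Ugt3a2 was at least 63.8-fold lower, Serpina4-ps1 at least 51.7-fold and Ces1f at least 41.2-fold. Saa1, Sult2a8, Cyp2c50, Ces1f and D17H6S56E-5 have close relatives or repeats in the genome, and their values are uncertain because probes can bind several of these.

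Genes of G2/M and mitosis rose together in LT against WT: 52 of 54 measured members were higher, 0 were lower and 2 were not past the rule of size, with a median log2 ratio of 2.32, which was 0.86 over 16 genes on the 430B design alone and 1.63 with a floor at the 75th percentile. Of 49 DNA replication and G1/S genes, 39 were higher and 0 lower (median 1.74), with Gins2 at least 16.0-fold, Mcm2 7.78-fold and Mcm6 7.48-fold higher. DNA damage response and repair genes had 16 of 33 members higher and 1 lower (median 0.96), among them Topbp1 (5.26-fold) and Fancb (4.99-fold). The E2F and pocket protein network had 11 of 27 higher and 0 lower (median 0.81, and 0.43 when scaled to the probe sets shared by both designs), with Tfdp1 4.38-fold and the kinase inhibitor Cdkn2c 3.98-fold higher. Each of these 4 medians lay above every one of 10000 random lists of like size and brightness. Mki67, the Ki-67 proliferation antigen, was 9.72-fold higher in LT, the replication clamp Pcna 4.16-fold, E2f1 at least 2.15-fold, and Rb1, at the floor in WT, had a log2 ratio of at least 0.42.

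Targets of p53 did not shift as a group in LT against WT: 2 of 26 measured members were higher, 1 was lower and 23 were not past the rule, with a median of 0.17, at the 81.1 percentile of random lists, which turned to -0.03 when arrays were scaled to the probe sets shared by both designs. Cdkn1a, which encodes the cell cycle inhibitor p21, was 4.11-fold higher, Ckap2 3.49-fold higher and Dcxr 6.86-fold lower. Mdm2, whose product degrades p53, had a log2 ratio of 0.63 and Ccng1 one of -0.94. Other probe sets gave 0.78 for Mdm2 and -0.53 and 0.64 for Ccng1, and a 430B probe set of Mdm2, at the floor in LT, gave -0.74 or lower. Trp53 itself was not analysed here.

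Immediate early and AP-1 genes had 8 of 18 members higher in LT than in WT and 0 lower (median 0.84), with Egr1 7.34-fold and Klf6 2.85-fold higher. Ribosome biogenesis genes had 10 of 27 higher (median 0.74), Rrn3 by 3.54-fold and Noc2l by 3.17-fold. Ribosomal protein genes had a median of 0.71, but only 2 of 28 passed the rule, Rpl12 (at least 2.55-fold) and Rps3 (2.16-fold). Of 13 oncofetal and imprinted genes, 6 were higher and 1 lower (median 0.51, from 0.07 to 1.46 under the 6 scalings and -0.04 on the 430B design alone), with Gpc3 9.83-fold, Igf2 at least 8.59-fold and Peg3 4.53-fold higher.

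Hepatocyte metabolism fell broadly in LT against WT. Cytochrome P450 and xenobiotic metabolism genes had 35 of 53 members lower and 1 higher (median -1.78). Sterol and fatty acid synthesis genes had 32 of 39 lower and 1 higher (median -1.88), with Elovl3 at least 32.1-fold and the sterol oxidase gene Msmo1 11.7-fold lower. Growth hormone and male-biased genes had 15 of 21 lower and 0 higher (median -1.93), with Hsd3b5 at least 27.6-fold and Mup3, of the paralogous major urinary protein family and so uncertain, 19.8-fold lower. Urea cycle and amino acid catabolism genes had 23 of 40 lower and 0 higher (median -1.18), Haao by 16.6-fold and Agxt by 15.5-fold. Bile acid and cholesterol catabolism genes had 14 of 26 lower and 1 higher (median -1.03), Slco1b2 by 22.5-fold and Slc27a5 by 13.9-fold. Gluconeogenesis and glycogen genes had 12 of 23 lower and 1 higher (median -1.05, and 0.14 over 5 genes on the 430B design alone), Igfbp1 by 6.46-fold and Pygl by 5.13-fold. Plasma protein genes had 19 of 41 lower and 0 higher (median -0.96), with C8a 12.2-fold and Mbl2 10.2-fold lower, while Alb had a log2 ratio of -0.25 and Apoe was 3.15-fold lower. Acute phase genes went both ways, with 9 of 23 lower and 4 higher (median -0.64, from -0.90 to -0.18 under the 6 scalings), Orm1 26.6-fold lower and the iron hormone gene Hamp 6.85-fold higher. These 8 medians lay at or below the 0.245 percentile of random lists. Under the 6 scalings the values nearest 0 were -1.32 for cytochrome P450, -1.42 for sterol and fatty acid synthesis and -1.47 for growth hormone genes. They were -0.72 for urea cycle, -0.57 for bile acid, -0.67 for gluconeogenesis and -0.50 for plasma protein genes.

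The lists for other pathways stayed within the middle 95% of random lists in LT against WT, among them fatty acid oxidation and PPARA targets (median -0.16, with 2 of 35 higher and 7 lower, Acot2 at least 14.3-fold higher and Acaa1b 6.90-fold lower), hepatocyte transcription factors (0.11), apoptosis regulators (-0.14), circadian clock (-0.20), interferon response (-0.10), stress and unfolded protein response (-0.11), proteasome (0.22) and oxidative phosphorylation (-0.08). The signs of these medians depended on the scaling, and each turned under at least 1 alternative. Of 3 measured germ-line genes, Syce2 was at least 3.13-fold higher.

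Among markers of other liver cells, the medians in LT against WT were -0.17 for Kupffer cells and macrophages, -0.44 for endothelial cells, -0.30 for stellate cells and matrix, -0.50 for B cells and plasma cells, 0.48 for neutrophils, -0.15 for T and NK cells and -0.12 for erythroid cells and blood, of which the Kupffer, stellate and erythroid medians turned positive when scaled to the hybridisation controls. Of these, endothelial cells (3 of 16 lower, Tek by 2.31-fold and Cdh5 by 2.27-fold), B cells (3 of 10 lower, Ighm by 2.52-fold) and neutrophils (2 of 8 higher, S100a8 by at least 2.53-fold and Lcn2 by 2.48-fold) lay outside the middle 95% of random lists. Pancreas acinar genes had a median of -0.83 over 5 genes (from -0.93 to -0.40 under the 6 scalings), at the 0.70 percentile, with Cela1 7.28-fold lower. Among bile duct and progenitor genes, Prom1 was at least 6.09-fold and Cd24a at least 6.03-fold higher. Muscle and adipose genes had fewer than 5 measured members, of which Fabp4 was 2.04-fold lower.

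RNA quality moved with genotype too. The 3' over 5' ratio of the Gapdh control, which rises when RNA is broken or copied short, was 5.81 on the 430A and 6.04 on the 430B array of WT, 3.08 and 3.16 for LT, and 3.53 and 2.85 for 17kT. The same ratio of the Actb control was 2.57 and 2.29 for WT, 2.52 and 2.50 for LT, and 2.13 and 1.72 for 17kT. LT arrays were washed on fluidics station 2 and the WT and 17kT arrays on station 1, so that station and LT genotype cannot be told apart.

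The balance of calls in LT against WT hung on scaling. In the setting used here 55.2% of called genes were higher, against 27.0% when arrays were scaled to the probe sets shared by both designs and 82.0% when scaled to the hybridisation controls, which moved the median of all measured genes from 0.02 to -0.27 and 0.41. Relative to the median of all genes, the G2/M median lay between 2.18 and 2.36 and the cytochrome P450 median between -1.89 and -1.56 under the 6 scalings. That subtraction cancels most of what a scaling changes. Without it the ranges were 1.99 to 2.61 and -2.08 to -1.32. On simulated arrays with the spread between probe sets of a gene, 317 of 12155 unchanged genes were called higher and 360 lower. Among the changed genes, all with a mean signal well above the floor, 4-fold changes were recovered for 92.0% and 2-fold changes for 38.0%.

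**Figure D1:**
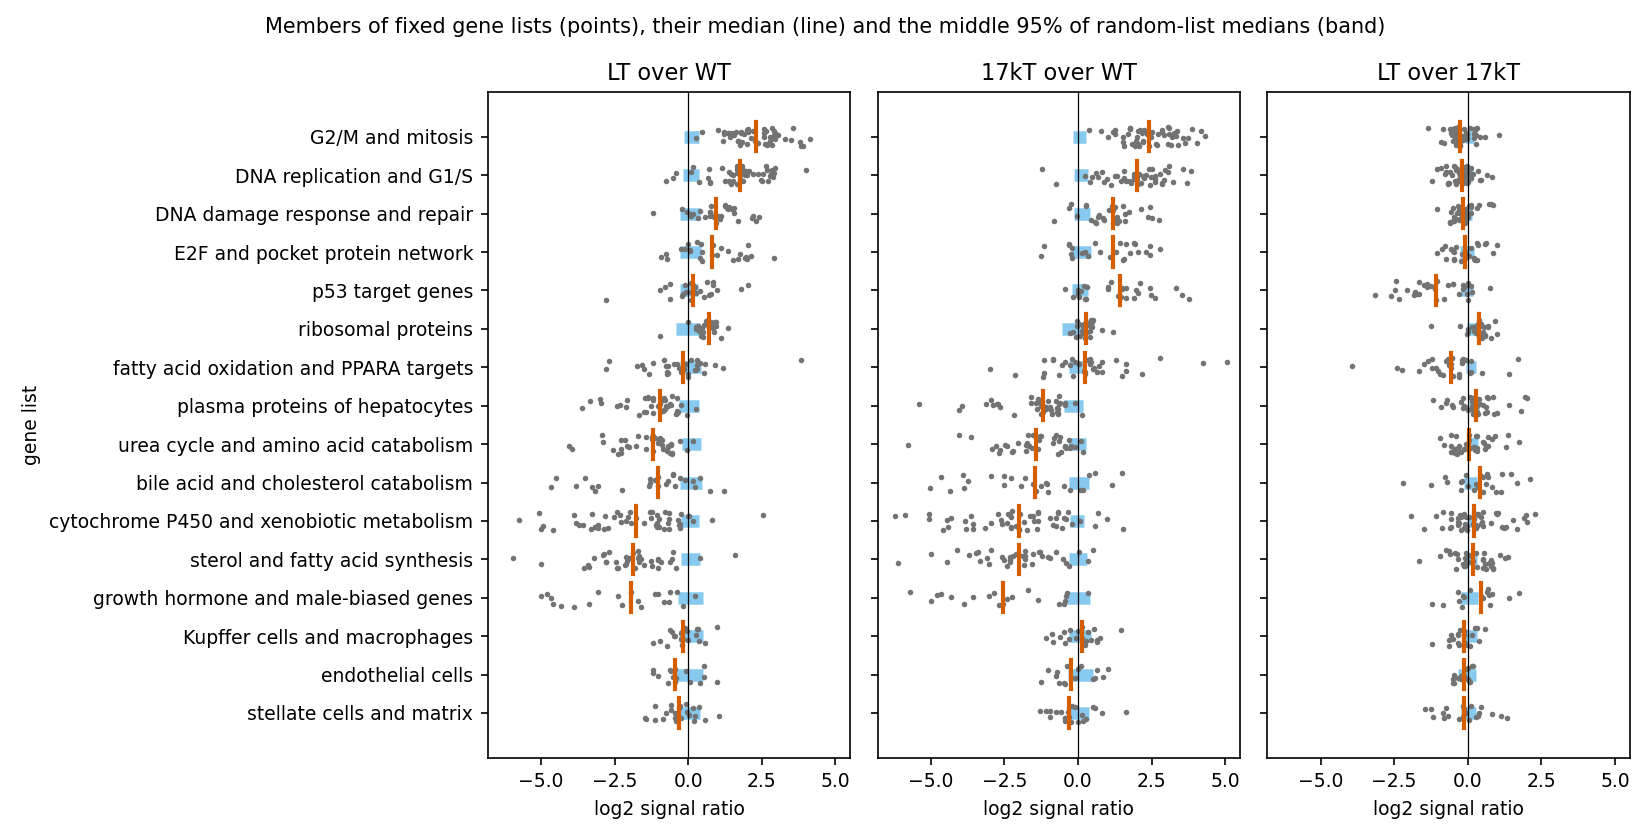
Log2 signal ratios of single members (points) of 16 gene lists fixed before the data were examined, for LT over WT, 17kT over WT and LT over 17kT, with the list median (vertical line) and the middle 95% of medians of 10000 random lists (band). G2/M genes centre on 2.32 and 2.43 against WT and on -0.27 between the transgenic livers, while p53 targets centre on 0.17, 1.42 and -1.10.

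The comparison of 17kT with WT asked the same of livers induced to make the short form, which does not bind p53. 17kT liver also rose in cell division genes and fell in hepatocyte metabolism, and p53 target genes rose with them. Top2a was 19.8-fold higher, Ccnb2 16.7-fold, the ribonucleotide reductase gene Rrm2 14.4-fold and the mitotic kinase gene Pbk 13.9-fold. Cdkn1a was 13.7-fold higher. Sult2a8 was 78.9-fold lower and Thrsp 69.6-fold. In all, 1295 of 12992 measured genes were higher in 17kT and 1123 were lower.

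Further large increases in 17kT against WT were in Acot1, an acyl-CoA thioesterase gene (18.9-fold), Tubb6 (17.4-fold) and D17H6S56E-5 (15.3-fold). Acot2 was at least 33.0-fold higher, though it is a close paralog of Acot1 and both are uncertain. Tnfrsf12a, the TWEAK receptor, was at least 19.9-fold higher and the survivin gene Birc5 at least 17.9-fold. Large decreases were in Saa1 (68.3-fold), Haao (54.7-fold), Ugt3a2 (54.7-fold), the immunoglobulin receptor Pigr (50.8-fold), Keg1 (46.3-fold) and Mug1 (35.9-fold). Cyp2c50 was at least 75.03-fold lower, Cyp2j5 at least 58.2-fold and Mup3 at least 52.3-fold. Saa1, Mug1, Mup3 and the Cyp2c and Sult2a genes belong to families of close paralogs and are uncertain.

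Among p53 targets in 17kT against WT, 19 of 30 measured members were higher, 0 were lower and 11 were not past the rule, with a median of 1.42, above every random list. Psrc1 was at least 11.6-fold higher, Ptp4a3 9.99-fold, Ckap2 6.12-fold, Mdm2 4.07-fold and Ccng1 2.17-fold. Ckap2, Gtse1 and Psrc1 are also genes of dividing cells. The rise rests on the 430A design, since the median was -0.004 over the 8 members measured on the 430B design, where another probe set of Mdm2, at the floor in 17kT, gave a log2 ratio of -0.74 or lower.

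G2/M and mitosis genes had 53 of 55 members higher in 17kT than in WT and 0 lower (median 2.43, and 1.31 over 16 genes on the 430B design alone), with Bub1b at least 14.7-fold higher. DNA replication and G1/S genes had 39 of 49 higher and 1 lower (median 2.02, from 1.86 to 2.64 under the 6 scalings), Mcm2 by 12.9-fold. DNA damage response and repair genes had 20 of 33 higher and 0 lower (median 1.19), H2ax by 6.72-fold and Brca1 by at least 5.71-fold. The E2F and pocket protein network had 14 of 26 higher and 2 lower (median 1.19), Cdkn3 by 6.89-fold and Rbl1 by 5.40-fold. Mki67 was 12.3-fold higher, Pcna 4.75-fold, E2f1 at least 3.06-fold and Rb1 at least 2.45-fold. Immediate early and AP-1 genes had 6 of 18 higher and 0 lower (median 0.51, from 0.46 to 1.14 under the 6 scalings), with Egr1 11.2-fold and Jun 3.37-fold higher. Ribosomal protein genes had a median of 0.27, from 0.04 to 1.15 under the 6 scalings, with 1 of 28 higher, Rps25 by at least 2.27-fold.

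The metabolic groups fell in 17kT against WT as well. Growth hormone and male-biased genes had 15 of 21 members lower and 0 higher (median -2.54), sterol and fatty acid synthesis genes 31 of 39 lower and 0 higher (-2.01, Insig1 by 21.6-fold and the fatty acid synthase gene Fasn by 11.1-fold), and cytochrome P450 and xenobiotic metabolism genes 38 of 54 lower and 1 higher (-1.99, Ugt2b1 by 33.5-fold). Bile acid and cholesterol catabolism genes had 18 of 26 lower and 2 higher (-1.47), with Slco1b2 32.4-fold and the bile acid importer gene Slc10a1 20.2-fold lower. Urea cycle and amino acid catabolism genes had 24 of 40 lower and 0 higher (-1.43, Kynu by 12.4-fold), gluconeogenesis and glycogen genes 14 of 23 lower and 1 higher (-1.19, the glucagon receptor gene Gcgr by 13.7-fold) and plasma protein genes 25 of 41 lower and 0 higher (-1.18). Under the 6 scalings the values nearest 0 of these 7 medians were -1.80 for growth hormone, -1.23 for sterol and fatty acid synthesis, -1.28 for cytochrome P450, -0.58 for bile acid, -0.66 for urea cycle, -0.33 for gluconeogenesis and -0.30 for plasma protein genes. C8a was at least 42.5-fold lower and Apoa2 16.3-fold. Alb had a log2 ratio of -0.63, Apoe one of -0.92, and Afp was at least 2.47-fold higher. Cebpa, a transcription factor of mature hepatocytes, was 4.17-fold lower, while the 18 hepatocyte transcription factors had a median of -0.09, which turned positive when scaled to the hybridisation controls.

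Acute phase genes had 9 of 23 members lower and 6 higher in 17kT than in WT, with Orm1 24.2-fold lower and the metallothionein genes Mt1 and Mt2 12.3-fold and 10.7-fold higher, and their median of -0.58 became 0.26 when arrays were scaled to the hybridisation controls. Stress and unfolded protein response genes had 7 of 29 lower and 2 higher (median -0.52, and 0.27 under that scaling), with Pdia6 2.91-fold lower and Hmox1 2.75-fold higher. Interferon response genes had 5 of 35 lower and 1 higher (median -0.22, and 0.62 under that scaling), Gbp6 by 5.45-fold. Medians within the middle 95% of random lists were 0.26 for fatty acid oxidation and PPARA targets (8 of 37 higher, 5 lower), -0.37 for oxidative phosphorylation, 0.22 for the circadian clock (5 of 14 higher, Per1 by at least 6.14-fold), -0.14 for oncofetal and imprinted genes, 0.16 for apoptosis regulators (Bcl2l11, which encodes the cell death factor Bim, 4.41-fold higher), 0.33 for ribosome biogenesis (3 of 27 higher, Nop58 by 3.27-fold) and 0.12 for the proteasome, with signs that depended on the scaling except for fatty acid oxidation, the clock and ribosome biogenesis. Of 3 germ-line genes, Syce2 was at least 3.84-fold higher.

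Beside these groups, markers of other cells in 17kT against WT had medians of 0.13 for Kupffer cells and macrophages, -0.24 for endothelial cells, -0.11 for T and NK cells, 0.32 for neutrophils and -0.23 for erythroid cells and blood, and all but the neutrophil median changed sign under at least 1 scaling. Below the middle 95% of random lists were B cells and plasma cells (median -0.69, at most -0.05 under the 6 scalings, 5 of 10 lower, Ighm by 2.95-fold) and stellate cells and matrix (median -0.31, 2 of 24 lower, Sparc by 2.46-fold, and 0.44 when scaled to the hybridisation controls). Pancreas acinar genes had a median of -0.26, with Cela1 5.51-fold lower. Fabp4, an adipose gene, was 2.33-fold lower, and no measured muscle or bile duct gene passed the rule of size.

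Of the genes called in 17kT against WT, 53.6% were higher, against 42.9% when scaled to the probe sets shared by both designs and 86.3% when scaled to the hybridisation controls, with medians of all genes of 0.07, -0.05 and 0.53. Under the hybridisation controls the median of probe sets above the floor was 0.95 on 430A and 0.11 on 430B. Relative to the median of all genes, the p53 target median lay between 1.34 and 1.38 under the 6 scalings and the cytochrome P450 median between -2.14 and -1.75. Without that subtraction, which cancels most of what a scaling changes, the ranges were 1.29 to 1.91 and -2.19 to -1.28. Simulated arrays gave 295 of 12143 unchanged genes called higher and 285 lower. Among the changed genes, all with a mean signal well above the floor, 4-fold changes were recovered for 88.0% and 2-fold changes for 46.0%.

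**Figure D2:**
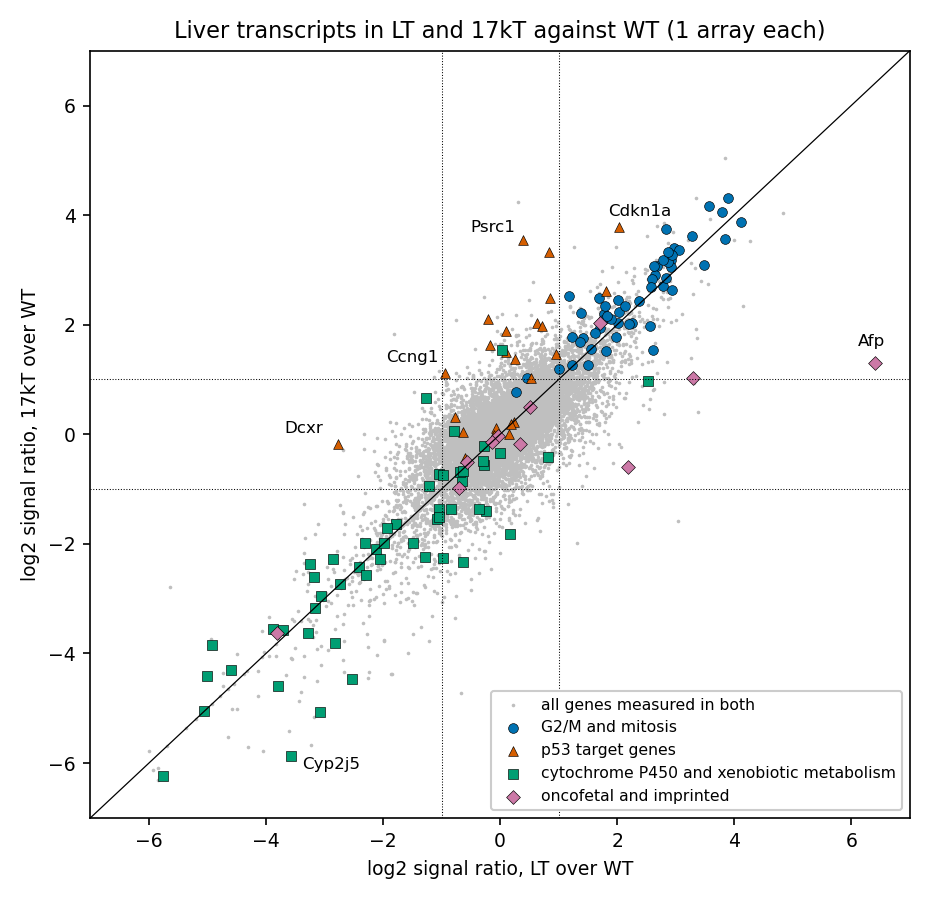
Log2 signal ratio of LT over WT (horizontal axis) against that of 17kT over WT (vertical axis) for 12462 genes measured in both comparisons (grey), with 4 gene lists in colour; dotted lines mark 2-fold and the solid line equal ratios. Most coloured genes of G2/M and cytochrome P450 metabolism lie along the diagonal, p53 targets such as Cdkn1a (2.04 and 3.78) lie above it, and Afp (at least 6.41 and 1.30) lies below it.

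The genes changed in LT and in 17kT overlapped. Of the 1376 genes higher in LT among those measured in both comparisons, 765 (55.6%) were also higher in 17kT, and of 1151 lower in LT, 698 (60.6%) were also lower. Independent lists of these sizes would share 138 and 104 genes. Across the 12462 genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.81 and Spearman's rho 0.74, and the covariance was 0.68. Both comparisons used the same WT arrays, and simulated unchanged arrays set against 1 shared WT array, with technical noise and no variation between animals, gave r of 0.51, a covariance of 0.12, and 40.0 and 47.4 shared genes (mean of 100 draws). The difference in covariance was 0.56. The single WT array per design could not be split, so part of the excess may come from the shared controls, including what was particular to the WT sample. With LT against WT taken from 430A and 17kT against WT from 430B, which share no array, r was 0.35 over 1734 genes (covariance 0.21). The reverse gave 0.32 over 1776 genes (covariance 0.21). Both still share the WT sample, so what was particular to that sample is not removed. The same comparison on both designs gave r of 0.38 for LT (covariance 0.24) and 0.37 for 17kT (0.23).

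The direct comparison of LT with 17kT asked where large T and its short form differed. In LT, 18 of 32 p53 target genes were lower than in 17kT, 10 of 37 fatty acid oxidation genes were lower as well, and 5 of 11 oncofetal and imprinted genes were higher. Psrc1 was 8.88-fold lower in LT, the phosphatase gene Ptp4a3 5.57-fold, the antiproliferative gene Btg2 5.01-fold, Ccng1 4.17-fold, Cdkn1a 3.33-fold and Mdm2 2.62-fold. A second, dimmer probe set gave a log2 ratio of 0.01 for Btg2, and one for Mdm2 gave -0.66, not past the rule of size. Afp was 34.6-fold higher in LT, Igf2 at least 8.59-fold and Peg3 6.87-fold. In all, 561 of 12541 measured genes were higher in LT and 531 lower.

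Of the other single genes, the carbonic anhydrase gene Car3 was 16.5-fold higher in LT than in 17kT, Epn2 9.84-fold, Lgals2 7.88-fold, Ang 5.99-fold, Afm 5.87-fold and Apom 5.79-fold. The Epn2 probe set used read 150 in 17kT, near the floor of 140.5. Its other probe sets above the floor in LT or 17kT gave log2 ratios of only 0.73 and 0.15. Bex1 was at least 18.02-fold higher and BC080696 at least 8.09-fold. Acot1 was 15.4-fold lower in LT, Ces2e 12.5-fold, Depp1 7.21-fold, Dcxr 6.09-fold and Ehhadh, a peroxisomal enzyme gene, 5.26-fold. Sulf2 was at least 7.19-fold lower, Gm6958 at least 6.83-fold and Mroh2a at least 6.51-fold. Ang, Ces2e and Acot1 have close paralogs and are uncertain.

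Among p53 targets in LT against 17kT, 18 of 32 measured members were lower, 0 were higher and 14 were not past the rule, with a median of -1.10, below every random list. Under the 6 scalings it lay between -1.48 and -0.94, and between -1.25 and -1.05 relative to the median of all genes. It was -0.21 over 7 members on the 430B design alone. Fatty acid oxidation and PPARA targets had 10 of 37 lower and 2 higher (median -0.58, below every random list), with Angptl4 4.65-fold, the pyruvate dehydrogenase kinase gene Pdk4 3.14-fold and the carnitine palmitoyltransferase gene Cpt1a 2.54-fold lower, and Vnn1 3.26-fold higher. Of 11 oncofetal and imprinted genes, 5 were higher in LT and 0 lower (median 0.52, at the 99.6 percentile, but 1.39 on the 430A design alone, 0.19 and 1.479 with floors at the 25th and 75th percentile, and 0.16 when scaled to the hybridisation controls), among them Cd24a at least 6.03-fold and Gpc3 4.81-fold. Cd24a also stands in the bile duct and progenitor list, where Prom1 was 3.48-fold higher (2 of 5 higher, median 0.59, at the 99.75 percentile).

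Few cell division genes passed the rule of size between LT and 17kT, though most were slightly lower in LT. G2/M genes had 1 of 55 higher (Bub1, 2.09-fold) and 1 lower (Kif4, 2.53-fold), with a median of -0.27, and DNA replication genes 2 of 49 lower (Uhrf1 by 2.34-fold and Rrm2 by 2.06-fold), with a median of -0.19. The G2/M median lay below every random list, with 43 of 55 members below 0. The DNA replication median lay at the 0.925 percentile, with 36 of 49 below 0. On the 430B design alone the 2 medians were 0.13 and 0.09. Mki67 had a log2 ratio of -0.34, Pcna -0.19, E2f1 -0.51 (other probe sets 0.10 and at least 0.13) and Rb1 -0.87. The E2F and pocket protein network had a median of -0.10, DNA damage response and repair genes -0.16, apoptosis regulators -0.13 and immediate early genes 0.13, all within the middle 95% of random lists and each of the other sign under 1 scaling.

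Among metabolic groups, bile acid and cholesterol catabolism genes had 5 of 25 members higher in LT than in 17kT and 2 lower (median 0.40, and -0.02 when scaled to the hybridisation controls), with Slc10a1 4.30-fold higher and the exporter gene Abcc2 4.56-fold lower. Growth hormone and male-biased genes had 2 of 17 higher and 1 lower (median 0.46), Igf1 by 3.33-fold. Oxidative phosphorylation genes had a median of 0.37 with none of 48 past the rule, and ribosomal protein genes one of 0.39 with 1 of 28 lower, medians that became -0.05 and -0.03 when scaled to the hybridisation controls. Acute phase genes had 4 of 21 higher and 4 lower (median -0.14, and 0.02 when scaled to the median of all probe sets), with Serpina3n 4.24-fold lower. Circadian clock genes had 3 of 14 lower and 0 higher (median -0.38, at the 2.34 percentile), Tef by 2.90-fold. Within the middle 95% lay plasma proteins (0.28), cytochrome P450 (0.20), sterol and fatty acid synthesis (0.19), gluconeogenesis (0.09), urea cycle (0.03), hepatocyte transcription factors (0.09, with Cebpa 2.27-fold higher), interferon (0.14), unfolded protein response (0.23), proteasome (0.07) and ribosome biogenesis (0.15), each of which turned negative when scaled to the hybridisation controls. Alb had a log2 ratio of 0.39 and Apoe one of -0.74.

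Beside these groups, the medians in LT against 17kT were -0.14 for Kupffer cells, -0.14 for endothelial cells, -0.11 for stellate cells, -0.03 for B cells, 0.23 for erythroid cells and 0.37 for neutrophils, each of the other sign under at least 1 scaling, and of these the neutrophil median lay outside the middle 95% of random lists (1 of 8 higher, S100a8 by at least 2.53-fold, and a median of -0.20 when scaled to the hybridisation controls). T and NK, pancreas, muscle and adipose lists had fewer than 5 measured genes, none past the rule of size.

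Of the genes called in LT against 17kT, 51.4% were higher, against 73.2% when scaled to the median of all probe sets and 20.8% when scaled to the probe sets shared by both designs, with medians of all genes of -0.03, 0.14 and -0.18. The 430B design supplied 382 of the genes higher and 351 of those lower from 5622 measured genes, and the 430A design 179 and 180 from 6919. Simulated arrays gave 118 of 12040 unchanged genes called higher and 139 lower. Among the changed genes, all with a mean signal well above the floor, 4-fold changes were recovered for 90.0% and 2-fold changes for 58.0%.

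**Figure D3:**
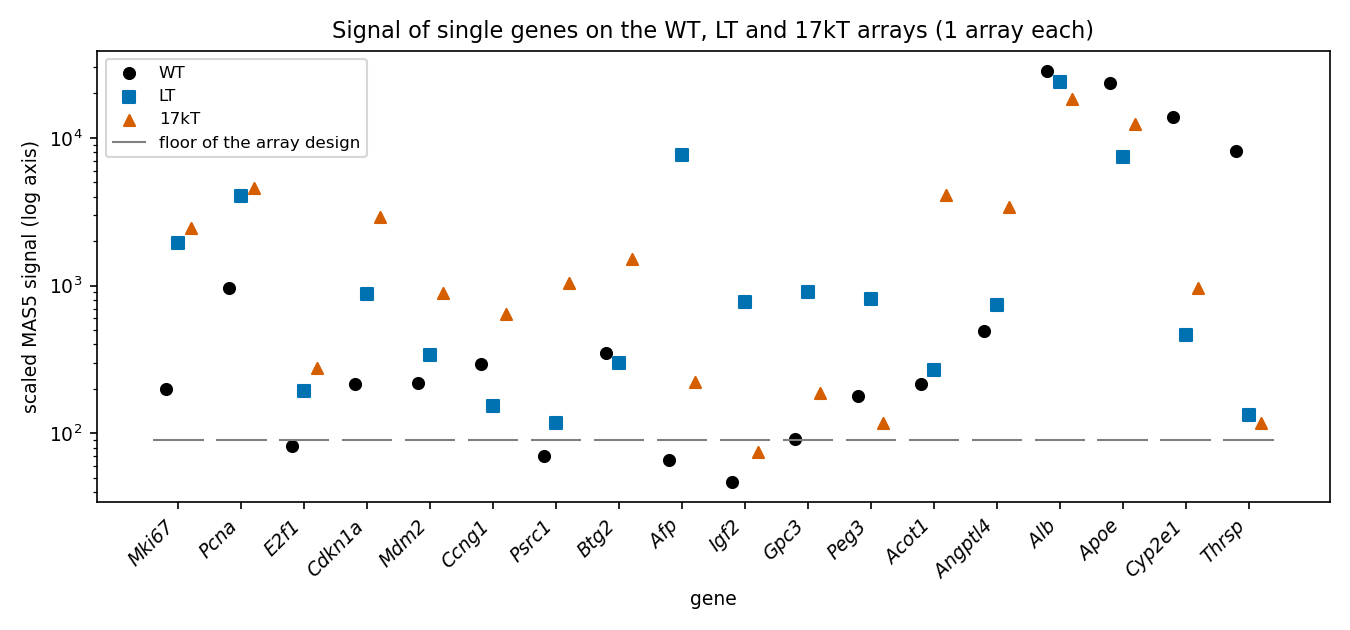
Scaled signal (log axis) of 18 genes on the WT, LT and 17kT arrays, with the floor of the array design as a grey line. Mki67 rises from 199 in WT to 1937 in LT and 2454 in 17kT, Cdkn1a from 215 to 881 and 2938, and Afp reads 7712 in LT and 223 in 17kT.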

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

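The tests of explanations below, and the scaling to hybridisation controls, were chosen after the results were seen.

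Genes that moved in opposite directions in the 2 transgenic livers were rare, and the difference was not tested. There were 3 genes at least 2-fold higher in LT and at least 2-fold lower in 17kT than in WT, Epn2 (log2 ratios 1.31 and -1.99), Hsd17b13 (3.03 and -1.58) and Rmdn1 (1.16 and -1.28 or lower), and 3 genes with the reverse, Ces2e (-1.81 and 1.83), Abcc2 (-1.04 and 1.15) and AA619741 (-1.13 or lower and 1.05). They were named after their values were seen. The second probe set of Hsd17b13, on the 430A design, gave -0.75 and 1.35, opposite to the first. The 430A probe sets above the floor gave 1.56 and 0.83 for Epn2 and -1.04 and -0.69 for Rmdn1, so neither gene moved in opposite directions there.

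The arrays carry control probe sets for repeated elements of the mouse genome that no comparison above used. The B1 repeat, a short interspersed element, read 1.51-fold higher in LT than in WT on the 430A design and 1.91-fold higher on the 430B design, while 17kT read 0.85 and 0.88 of WT. The B2 repeat read 0.66 and 0.72 of WT in LT and 0.61 and 0.69 in 17kT.

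The p53 target genes were lower in LT than in 17kT by a median of -1.10. Random lists of like brightness had medians between -0.22 and 0.17 in their middle 95%. The p53 list stood out by this same comparison. The comparison is therefore no separate test of a station shift common to probe sets of like brightness. A station effect on particular probe sets stays open too, because every LT array ran on its own station. The scaling of the arrays is argued against. The list median lay between -1.48 and -0.94 under the 6 scalings, with a technical SD of 0.26. That SD leaves out the offset between the designs, a median of -0.36 in this comparison, which was smaller in size than the list median. The choice of probe set stays open: 16 other probe sets of 13 of these genes, most of them dimmer, had a median of -0.36, with 14 below 0. On the 430B design alone the list median was -0.21 over 7 members. One hypothesis is that p53 stays active in 17kT liver and is held inactive in LT liver, since large T binds p53 and 17kT does not. It was not tested and would need p53 protein and its target transcripts measured in replicate livers. The list was not lower in LT than in WT: its median there was 0.17, with 2 of 26 members higher, Cdkn1a by 4.11-fold, and 1 lower.

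Genes of drug, bile acid, lipid synthesis, glucose and amino acid metabolism were lower in LT and in 17kT than in WT. A lower share of hepatocytes in the RNA, with hepatocytes themselves unchanged, would lower hepatocyte transcription factors as far as the 5 metabolic lists. For LT the median of the factors lay at least 0.997 above the lists under the 6 scalings (SD of the factors at most 0.73). This argues against a lower share as the only source in LT. It cannot exclude a lower share beside a fall within hepatocytes. Whether other liver cells make some of these factors was not checked. Markers of other cells in LT went both ways and do not decide the question. The endothelial median was at most -0.021 and the neutrophil median lay between 0.17 and 0.63 under the 6 scalings. The macrophage and stellate medians turned to 0.29 and 0.13 when scaled to the hybridisation controls. For 17kT a lower share stays open, at least as a part: the factors lay at least 0.81 above the lists, within their SD of up to 0.90. The macrophage, endothelial and stellate medians of 0.13, -0.24 and -0.31 in 17kT became 1.01, 0.64 and 0.44 when scaled to the hybridisation controls. That scaling raised the median of all genes to 0.53. The controls themselves had a median log2 ratio of 17kT against WT of -0.94 on 430A and -0.004 on 430B. The rise thus came mainly from a control difference on 430A that 430B did not repeat. Random lists of like brightness did not fall as far as the 5 lists, none of which lay above the 0.01 percentile in either comparison. The lists stood out by these same percentiles, so this is no separate test of a bias that depends on brightness. A bias among genes within 1 bin of brightness stays open. More degraded RNA in the WT sample may contribute and cannot be told apart here: the Gapdh 3' over 5' ratio was highest in WT on both designs, but the Actb ratio of WT was 0.91 of that of LT on the 430B design. The induced oncoproteins and the ApoErtTA transgene, which WT lacked, remain open biological explanations.

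Afp, Igf2, Gpc3, Cd24a and Peg3, a set picked after their values were seen, were higher in LT than in 17kT. The median of all genes lay between -0.23 and 0.14 under the 6 scalings, and the lowest of the 5 genes was at 1.85. Scaling therefore does not remove the difference in these 5 genes. As they were picked for large ratios, this is no test for the other genes of the oncofetal list. The median of that whole list went from 0.52 to 0.16 when scaled to the hybridisation controls. Bile duct or progenitor cells in the LT sample remain a possible source, because only 4 other markers of these cells were above the floor in either sample, and 1 of them, Prom1, was at least 2-fold higher, while Krt7, Krt19, Epcam and Sox9 lay at the floor in all samples. A difference between the oncoproteins stays open and was not tested.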

How the results depend on the processing

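The scaling to hybridisation controls was chosen after seeing the data. With 1 array per group, no replicate could be left out, and arrays limit what can be seen near the floor. No paired analysis was possible because each genotype had 1 array per design and no test was run. Using signals as deposited, or leaving out _x_at and _s_at probe sets, left each count within 1.5 times of that reported. Over all alternatives, 38 counts of called genes stayed within 1.5 times and 40 moved further, and of the list medians 912 stayed within 1 technical SD, 183 moved further, and 16 that had lain outside the middle 95% of random lists changed sign. Of values of named genes, 700 stayed within 1 technical SD, 327 moved further, and 1 past 2-fold changed sign. Counts moved under other floors and the 3-fold rule, and with a single design because fewer genes were measured. The cause of the other changes was not tested.

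Genes higher and lower in LT against WT numbered 798 and 2161 with scaling to the shared probe sets, 2728 and 599 with the hybridisation controls, 2176 and 2258 with the 25th percentile floor, 746 and 634 with the 75th, 484 and 428 at 3-fold, 858 and 679 on 430A only, and 720 and 587 on 430B only. In 17kT against WT they numbered 3881 and 618 with the hybridisation controls, 2180 and 1891 with the 25th percentile floor, 529 and 717 with the 75th, 436 and 508 at 3-fold, and 548 and 531 on 430B only, with 696 lower on 430A only. In LT against 17kT they numbered 868 and 317 with scaling to the median, 290 and 1106 with the shared probe sets, 1100 and 1397 with the 25th percentile floor, 311 and 156 with the 75th, 362 and 312 with a pseudocount, 136 and 86 at 3-fold, and 191 and 193 on 430A only, with 960 lower with the hybridisation controls. The correlation of LT and 17kT against WT was 0.69 on 430B only.

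The G2/M median in LT and 17kT against WT was 2.64 and 2.84 with the 25th percentile floor, 1.63 and 1.81 with the 75th, 1.92 and 1.91 with a pseudocount, 1.81 and 2.04 with the mean over probe sets, 0.86 and 1.31 on 430B only, and 2.61 and 3.22 with the hybridisation controls, and 1.99 in LT with the shared probe sets. The cytochrome P450 median in LT was -2.08 with the shared probe sets, -1.48 and -1.51 with the 25th and 75th percentile floors and -1.32 with the hybridisation controls, which gave -1.28 in 17kT. The p53 target median in 17kT against WT was 1.11 with a pseudocount, 0.86 with the mean over probe sets, 1.91 with the hybridisation controls and -0.0041 on 430B only, and in LT against 17kT -1.48 with the hybridisation controls and -0.21 on 430B only. The oncofetal median in LT against 17kT was 0.19 and 1.479 with the 25th and 75th percentile floors, 1.39 on 430A only and 0.16 with the hybridisation controls.

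Signs changed on 430B only for DNA replication (0.093) and G2/M (0.13) in LT against 17kT, for oncofetal (-0.038) and gluconeogenesis genes (0.14) in LT against WT, and for p53 targets (-0.0041), stellate genes (0.72) and Mdm2 (-0.74 or lower) in 17kT against WT. Acute phase genes in LT against 17kT changed sign with scaling to the median (0.021) and the 75th percentile floor (0.024). With the hybridisation controls, signs changed in 17kT against WT for acute phase (0.26), interferon (0.62), unfolded protein response (0.27) and stellate genes (0.44), and in LT against 17kT for bile acid (-0.017), ribosomal protein (-0.030), oxidative phosphorylation (-0.048) and neutrophil genes (-0.20).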

Other observations

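The test of fasting below was chosen after the result was seen, and that of neighbouring genes before.

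Car3 read 16335 in WT, 10259 in LT and 621 in 17kT, which makes it 26.3-fold lower in 17kT than in WT with a log2 ratio of -0.67 in LT. It was chosen here after its values were seen. The probe set chosen for Slc25a4, the carrier of heart and muscle mitochondria, was at the floor in WT and read 1754 in LT and 1045 in 17kT. Of the other probe sets of Slc25a4, 2 gave 1533 and 2843 in LT, the latter with 93.7 in WT, above the floor of 90.4, and 1 was at the floor in all 3 genotypes.

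Of 37 fatty acid oxidation genes, 10 were higher in 17kT than in LT and 2 lower, and one hypothesis is that the 17kT animals had fasted. Of Pck1, G6pc, Igfbp1, Tat and Ppargc1a, genes that fasting raises in liver, 3 were higher in 17kT than in LT (log2 ratios of LT against 17kT of -0.89 for Pck1, -1.26 for Igfbp1 and -0.40 for Tat), and G6pc (0.28) and Ppargc1a (0.47) were not, so that fasting may or may not account for the pattern.

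The mice were of a hybrid background, and blocks of chromosome inherited from 1 parent strain could make neighbouring genes differ together between single samples. Of 12515 genes with a place in the annotation, 46 pairs of neighbours with unlike names were called the same way between LT and 17kT, and 1000 shuffles of the calls gave 33 to 58 such pairs in their middle 95%. Neighbours called the same way were thus no more common than in shuffled calls. Pairs called in opposite ways were not counted, so blocks that raise some genes and lower others stay open.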
